A study of Solanum lycopersicum with 12 samples.

How the data were processed

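Whole wild-type seedlings of tomato (Solanum lycopersicum) were moved 3 days after germination into liquid Murashige and Skoog medium, and were kept there for 8 days at 22 °C with 16 h of light and 8 h of darkness, per the labels' protocols. Fresh medium with 0.1% DMSO (mock), 10 µM of the hormone abscisic acid (ABA), 20 µM iSB09 or 10 µM iCB was then given for 3 h. A DMSO content was recorded for the mock medium only. A difference in solvent between groups therefore cannot be told apart from treatment. Each of the 4 treatments has 3 samples, which the series' design text calls independent biological replicates; nothing further is stated about what was independent between them. RNA was extracted with a plant RNA kit, and strand-specific mRNA libraries were made for DNBSEQ sequencing, per the labels' protocols.

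The values used are read counts per gene, which the authors deposited as 1 table of whole numbers for 34075 gene IDs. The submitters' processing notes name FastQC, cutadapt, STAR and DESeq2, without versions or roles. The genome build, the annotation, the counting step and whether counting used strand are not given in the sources used here. Reads from overlapping genes on opposite strands, and from near-identical copies in gene families such as those of the receptors, phosphatases and light-harvesting proteins, may therefore have been divided between IDs in ways that the table cannot show. The table's columns were matched to samples by name. The 9 columns of mock, ABA and iSB09 were matched, and 3 further columns, whose name occurs in no label of the series, were not used. The 3 iCB samples thereby have no matched column, so the iCB treatment is not analysed here, and every fit planned over 12 libraries was made over 9.

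The 9 libraries held between 21863058 and 22098966 counts each, and 3 counts over the 3 libraries of a group, the floor used here, correspond to 0.045 to 0.046 CPM, the count scaled to library size. Of the 34075 IDs, 7403 had no read in these libraries, and 21424 passed edgeR's filterByExpr and were tested. Intervals and floors based on counts cover counting error only. Within groups, no pair of libraries agreed within sampling noise: chi-square per degree of freedom over genes lay between 7.465 and 28.48.

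Differences were tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) normalisation, 1 coefficient per treatment, no replicate term, and the two-sided quasi-likelihood F test (glmQLFit and glmQLFTest). All 9 libraries entered 1 fit, so that the groups shared an estimate of the spread; the common biological coefficient of variation was 0.14. Adjusted p is the Benjamini-Hochberg value over the 21424 genes, and a gene is said to rise, fall or change when it is under 0.05. Standard errors (SE) of log2 fold changes come from the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Where a group had 0 counts, a fold was computed against 3 counts over the group's libraries and is a lower bound; where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval.

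Gene lists were fixed before the data were examined. The table and the reference given for this work do not pair its IDs with names: 0 entries of the RefSeq gene table hold an ID of this kind. No symbol is therefore given. Lists contain IDs written down beforehand, from general knowledge, as members of published tomato gene families. That membership was not checked against an annotation here, and the description patterns meant to extend and check the lists were not applied. Of 27 lists, 18 held IDs, 127 in all, of which 122 were in the table and 111 were tested; 9 lists had at least 5 tested members. Lists without IDs, among them ribosomal proteins, aquaporins and auxin response, have no result, nor was the share of organelle transcripts computed. The 9 lists were tested with limma 3.58.1's camera on log2 CPM with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over those 9, and again with the correlation estimated from the data; fry was a further alternative. The genes named were chosen by a rule fixed beforehand. It allows up to 3 members with the smallest adjusted p of each ABA-signalling or ABA-metabolism list and of each other list past camera's threshold, or up to 2 for iSB09 against ABA. For genes outside the lists it allows, without names, the 2 IDs that rose most and the 2 that fell most, with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. The ranking uses fitted log2 fold changes, which depend on the prior count where a group has 0 to 3 counts, so it is not a ranking of the bounds and ratios printed. Genes named outside it are said to have been chosen after their values were seen.

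Because ABA and iSB09 were compared with the same mock libraries, 20 simulations of unchanged groups gave the agreement that shared controls produce alone. Because unchanged groups give almost no calls, the overlap of lists was simulated separately, after it had been seen: in 20 simulations the observed iSB09 changes were dealt to other genes of like abundance. Both kinds of simulation redrew the mock counts as well and drew genes independently of each other. Their maxima are therefore not bounds for data with correlated genes. Splitting 3 mock libraries leaves fewer than 2 on a side, so controls were not split. The procedure was tested on simulated counts for 21424 genes with 200 changed. For ABA against mock, 71% of changes of 1 log2 unit and 94% of changes of 2 were recovered. The values were 68% and 93% for iSB09 against mock, and 73% and 97% for iSB09 against ABA. Among genes left unchanged, 4, 18 and 8 were called in these comparisons, in that order. A test of iSB09 against a fixed fraction of the ABA change was tried over 21424 genes with 200 departing. It recovered 76% of departures of 1 log2 unit and 94% of 2, and called 7 genes that did not depart. A list planted with a change of 1 log2 unit in the ABA against mock simulation had adjusted p = 8.1e-27, and 0 of the other lists passed. Alternatives were other size factors, library totals, other filters on low counts, DESeq2 1.42.0, limma voom, fits of the 6 libraries compared, a replicate block, a test against a 2-fold change, removal of the 20 most abundant genes, and omission of each library in turn.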

Results

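The transcriptomes of tomato seedlings were compared after 3 h in mock solution, 10 µM ABA or 20 µM iSB09, a compound that the series tests for its ability to elicit ABA-responsive gene expression. Each group had 3 libraries. Total counts were 21903348 to 22098966 in mock, 21863058 to 22033066 in ABA and 21915024 to 21984149 in iSB09 libraries. Gene families are those of lists written beforehand from general knowledge; membership was not checked against an annotation, so each family name below is as sure as that list. The first principal component of log2 CPM held 58.29% of the variance and placed mock libraries between -61.3 and -48.7, iSB09 libraries between -6 and 8.5, and ABA libraries between 50.7 and 55.7. The second held 11.97%, with iSB09 replicate 2 at 45.5 and mock replicate 3 at -31.2 at its ends.

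The comparison of ABA with mock gives the response to the hormone, together with any difference in solvent. Listed clade A PP2C phosphatases, which repress ABA signalling until a hormone-bound receptor inhibits them, rose in 7 of 9 cases, with a median log2 fold change of 2.54. Solyc03g096670.3 rose from 4.59 ± 0.561 CPM in mock to 256 ± 37 CPM in ABA (SD, n = 3), a log2 fold change of 5.80 ± 0.15 (SE; adjusted p = 8.6e-09). Solyc07g040990.4 rose by 3.29 ± 0.11 on the log2 scale (adjusted p = 3.4e-08). Listed ABA receptors went the other way: 9 of 14 fell, 0 rose (1 at an unadjusted p under 0.05; 0 with DESeq2 and with limma voom), and the median log2 fold change was -0.88. Solyc10g085310.1 fell from 31.9 ± 1.08 to 5.51 ± 1.56 CPM, a log2 fold change of -2.53 ± 0.19 (adjusted p = 4.7e-06). Solyc06g050500.2 had a log2 fold change of -1.83 ± 0.19 (adjusted p = 4.8e-05).

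The remaining signalling lists rose in part. Of 7 SnRK2 kinases, which the phosphatases hold inactive, 3 rose, with small changes that reached 0.54 ± 0.09 on the log2 scale in Solyc04g012160.4 (adjusted p = 0.0014). Of 6 AREB/ABF/ABI5 bZIP transcription factors, which SnRK2 kinases activate, 4 rose, among them Solyc04g078840.3 by 2.42 ± 0.10 (adjusted p = 8.2e-08) and Solyc01g108080.4 by 1.77 ± 0.10 (adjusted p = 1.1e-06). Among 5 ABA biosynthesis genes 2 rose; Solyc07g056570.1 went from 7.51 ± 0.922 to 37.5 ± 7.59 CPM, a log2 fold change of 2.32 ± 0.22 (adjusted p = 2.3e-05). The other biosynthesis gene, Solyc07g066480.3, had 0.44 ± 0.12 (adjusted p = 0.024), a call that ended with library totals (adjusted p = 0.061), without mock replicate 1 or 2 (0.057 and 0.062) and without ABA replicate 1, 2 or 3 (0.061, 0.082 and 0.06). Solyc08g016720.1 had a log2 fold change of -0.99 and did not pass (adjusted p = 0.052), but did with DESeq2 (0.049), library totals (0.044), a filter of at least 1 CPM (0.05 before rounding), only the 6 libraries compared (0.011), and without iSB09 replicate 1 or 3 (0.045 and 0.01). Of the SnRK2 calls that of Solyc05g056550.3, at 0.49 ± 0.14 (adjusted p = 0.033), ended without mock replicate 3 (0.093) or ABA replicate 1 or 2 (0.13 and 0.066). Among 4 ABA catabolism genes 3 rose, led by Solyc08g075320.4 with 4.44 ± 0.13 (adjusted p = 2e-08).

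Protective proteins rose as well. Of 9 LEA, dehydrin and ASR genes, whose products accumulate in drying tissue, 7 rose and 1 fell, with a median log2 fold change of 1.36. Solyc02g084850.3 rose from 5.58 ± 0.651 to 517 ± 78.6 CPM, a log2 fold change of 6.53 ± 0.23 (adjusted p = 3.7e-08). Solyc03g116390.4 rose by 6.01 ± 0.67 (adjusted p = 8.9e-05), with mock libraries at 0.865, 0.747 and 6.967 CPM. Without mock replicate 3 its log2 fold change was 7.85. Both listed drought-linked NAC and HD-Zip factors rose, with log2 fold changes of 3.70 and 4.10, and 1 of 2 genes of raffinose, proline and trehalose synthesis rose. Of 4 expansins and xyloglucan endotransglucosylases 2 fell, of 4 ethylene genes 1 rose and 1 fell, of 3 heat shock genes 2 rose, and of 18 jasmonate and wound genes 3 fell and 0 rose (4 higher at an unadjusted p under 0.05; 0 with DESeq2, 1 with limma voom). For the jasmonate list the median log2 fold change was 0.00, the mean 0.13 and camera's direction down (adjusted p = 0.97), so these differ in sign. Without mock replicate 3, 1 jasmonate gene rose. The 3 falls became 1 without mock replicate 1, 0 without mock replicate 2, 2 without mock replicate 3 or iSB09 replicate 1, 1 without ABA replicate 1 and 0 without ABA replicate 2 or 3. Of the 2 heat shock genes 1 was left without mock replicate 1, 2 or 3 or ABA replicate 1 or 3, and 2 ethylene genes fell without mock replicate 1.

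Markers of tissue and time of day were measured beside these groups. None of 15 photosynthesis genes, which stand for the shoot, changed, at an unadjusted p under 0.05 or with DESeq2 or limma voom. Their median log2 fold change was -0.07 (camera adjusted p = 0.77). The list's mean log2 CPM, relative to all 9 libraries, was -0.23, -0.02 and 0.24 in ABA replicates 1 to 3. A difference between groups of the size of this spread could have been missed. The single tested root marker had a log2 fold change of 0.43 and did not pass (adjusted p = 0.27), and neither did the single gibberellin gene, at -0.29. Of 7 circadian clock genes 4 rose, with a median of 0.79, including Solyc12g056650.2 by 1.5 ± 0.12 (adjusted p = 7.9e-06) and Solyc04g071990.3 by 1.27 ± 0.08 (adjusted p = 1.7e-06). The clock list was set beforehand to stand for the time of harvest. A difference in harvest time between groups cannot be told apart from a response to treatment here, nor for the clock genes in the comparisons below.

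Over all genes, ABA raised 2091 and lowered 2120 of 21424 tested, 19.7% of them, and 931 and 891 of these changed at least 2-fold. Among IDs with at least 1 CPM in the higher group and no overlap between libraries, those that rose most by fitted fold change were Solyc06g060970.2, with 1223 counts against 1 in mock, a ratio of 1250 (95% interval 224 to 49500), and Solyc08g067230.4, at least 105-fold higher. Those that fell most by fitted fold change were Solyc06g072400.3, with 389 counts in mock against 1, a ratio of 380 (67.8 to 15000), and Solyc01g006310.3, with 0 counts in ABA and at least 31.9-fold lower, a bound that does not itself place it above other genes. The single counts were in mock replicate 1 and ABA replicate 1, and without these the fitted log2 fold changes of Solyc06g060970.2 and Solyc06g072400.3 went from 9.83 to 11.69 and from -8.12 to -10. In camera, PP2C phosphatases (adjusted p = 6.3e-10), receptors (5e-06), LEA proteins (4e-05), clock genes (0.00034) and bZIP factors (0.0021) passed. No list passed with an estimated correlation: adjusted p = 0.069 with an estimated correlation for the phosphatases, 0.087 for receptors, 0.07 for LEA proteins, 0.14 for clock genes and 0.07 for bZIP factors. SnRK2 kinases (0.062; 0.039 without mock replicate 3; 0.19 with an estimated correlation) and biosynthesis (0.22) did not pass camera, but passed fry (adjusted p = 0.0022 and 0.025). The medians of these lists had the same sign with median-of-ratios factors and with library totals. Adjusted over the list alone, 8 phosphatases, 3 SnRK2 kinases, 4 bZIP factors, 2 biosynthesis, 3 catabolism, 7 LEA and 4 clock genes rose. On the same basis 10 receptors fell and 1 rose, and 1 bZIP, 1 biosynthesis and 1 LEA gene fell. Without ABA replicate 2 or 3, the number of lowered genes was 1288 or 1406.

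**Figure D1:**
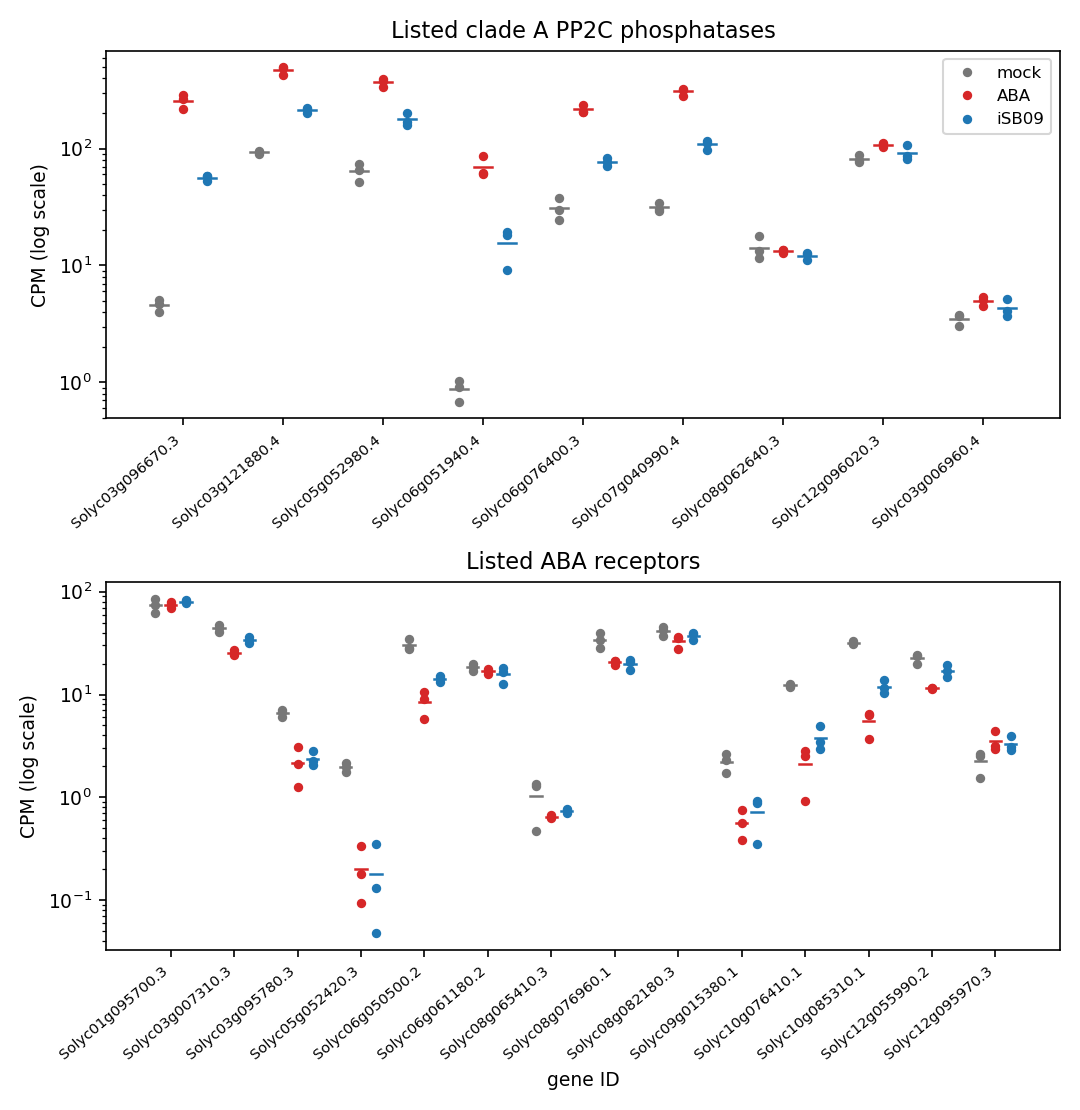
CPM (log axis) of each listed clade A PP2C phosphatase and ABA receptor with gene IDs along the horizontal axis; points are the 3 libraries of mock, ABA and iSB09, and horizontal lines their means. Of the 9 phosphatases 7 rose with ABA and 6 with iSB09; of the 14 receptors 9 fell with ABA and 8 with iSB09.

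The comparison of iSB09 with mock gives the response to the compound, at 20 µM, together with any difference in solvent. Of the 9 PP2C phosphatases 6 rose, with a median log2 fold change of 1.32. Solyc03g096670.3 reached 56.4 ± 3.21 CPM (SD, n = 3) from 4.59 ± 0.561, a log2 fold change of 3.62 ± 0.14 (adjusted p = 6.5e-07). Solyc06g051940.4 rose by 4.15 ± 0.33 (adjusted p = 6.4e-05). Of the 14 receptors 8 fell and 0 rose (1 at an unadjusted p under 0.05; 0 with DESeq2 and with limma voom), with a median of -0.63. Solyc10g085310.1 went to 11.9 ± 1.81 CPM, a log2 fold change of -1.42 ± 0.18 (adjusted p = 0.00089). Solyc05g052420.3 had -3.41 ± 0.47 (adjusted p = 0.0016), and -4.35 without iSB09 replicate 1. Of 9 LEA, dehydrin and ASR genes 4 rose, among them Solyc02g084850.3 by 4.51 ± 0.22 (adjusted p = 2.2e-06), to 127 ± 33.1 CPM, and Solyc03g116390.4 by 3.69 ± 0.64 (adjusted p = 0.0065; 5.53 on the log2 scale without mock replicate 3).

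Of the 6 bZIP factors 2 rose, Solyc04g078840.3 by 1.36 ± 0.10 (adjusted p = 2.5e-05) and Solyc01g108080.4 by 1.17 ± 0.10 (adjusted p = 8.8e-05). None of 7 SnRK2 kinases passed (1 higher at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma voom); Solyc04g012160.4 had a log2 fold change of 0.30 ± 0.09 (adjusted p = 0.084; 0.045 with DESeq2, 0.038 without iSB09 replicate 1). Among the biosynthesis genes Solyc07g056570.1 rose by 1.16 ± 0.22 (adjusted p = 0.01; 0.06 without mock replicate 2). Solyc08g016720.1 had -1.30 ± 0.33 (adjusted p = 0.046), a call that ended without mock replicate 1, 2 or 3 (adjusted p = 0.079, 0.1 and 0.11), ABA replicate 1, 2 or 3 (0.071, 0.075 and 0.075) or iSB09 replicate 2 or 3 (0.072 and 0.081). The call also ended with a replicate block (0.079) and with only the 6 libraries compared (0.11), and the value after ABA was -0.99. Of 4 catabolism genes 1 rose, Solyc08g075320.4, by 2.74 ± 0.13 (adjusted p = 2e-06). Both NAC and HD-Zip factors rose, with log2 fold changes of 2.63 and 1.92, and 1 of 2 genes of raffinose, proline and trehalose synthesis, 1 of 4 ethylene genes and 1 of 3 heat shock genes rose. Of 4 expansins and xyloglucan endotransglucosylases 1 fell, and of 18 jasmonate and wound genes 1 fell (4 at an unadjusted p under 0.05; 1 with DESeq2 and with limma voom). The expansin count was 0 without mock replicate 3 or iSB09 replicate 3 and 2 without iSB09 replicate 1. The jasmonate count was 0 without mock replicate 2 or iSB09 replicate 3, and the heat shock count 0 without mock replicate 1. Without iSB09 replicate 1, 1 SnRK2 kinase passed.

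None of the 15 photosynthesis genes changed, at an unadjusted p under 0.05 or with DESeq2 or limma voom, and their median log2 fold change was -0.13 (camera adjusted p = 0.31). Without mock replicate 3 or iSB09 replicate 2 this list passed camera's threshold (adjusted p = 0.0069 and 0.0048) with the preset correlation of 0.01; over all libraries the list's estimated correlation was 0.89, with adjusted p = 0.78. The list's mean log2 CPM, relative to all 9 libraries, was 0.19, 0.29 and -0.32 in mock replicates 1 to 3 and -0.14, 0.30 and -0.31 in iSB09 replicates 1 to 3. The root marker had a log2 fold change of -0.16 and the gibberellin gene -0.13, and neither passed. Of 7 clock genes 3 rose, with a median of 0.26, including Solyc12g056650.2 by 0.90 ± 0.12 (adjusted p = 0.0013) and Solyc04g071990.3 by 0.60 ± 0.08 (adjusted p = 0.0015). Without mock replicate 2 or iSB09 replicate 3, 2 clock genes rose.

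Over all genes, iSB09 raised 564 and lowered 531, 5.11% of those tested, and 313 and 250 of these changed at least 2-fold. Among IDs with at least 1 CPM in the higher group and no overlap between libraries, those that rose most by fitted fold change were Solyc07g042230.1, at least 27.8-fold higher than in mock, and Solyc06g060970.2, with 92 counts against 1, a ratio of 92.4 (95% interval 16.2 to 3690); without mock replicate 1 the fitted log2 fold change of the latter went from 6.07 to 7.94. Those that fell most by fitted fold change were Solyc12g100250.3, with a log2 fold change of -4.82 ± 0.50 (adjusted p = 0.00027; -5.72 without iSB09 replicate 1), and Solyc06g072400.3, with -4.25 ± 0.39 (adjusted p = 0.00011). Phosphatases (adjusted p = 2.2e-10), receptors (2.7e-06), LEA proteins (0.00013), clock genes (0.00064) and bZIP factors (0.0051) passed camera, and SnRK2 kinases (0.27), biosynthesis (0.25) and jasmonate genes (0.27) did not. No list passed with an estimated correlation: adjusted p = 0.062 with an estimated correlation for the phosphatases, 0.079 for receptors, for LEA proteins and for bZIP factors, and 0.16 for clock genes. Adjusted over the list alone, 6 phosphatases, 1 SnRK2 kinase, 3 bZIP factors, 1 biosynthesis, 1 catabolism, 7 LEA and 3 clock genes rose, and 9 receptors, 1 biosynthesis and 1 LEA gene fell. The number of lowered genes was 245 without mock replicate 2, 311 without iSB09 replicate 2, 249 without iSB09 replicate 3, and 319 when only the 6 libraries compared were fitted.

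The direct comparison of iSB09 with ABA asks where the responses differ; the doses differ too, at 20 µM for iSB09 and 10 µM for ABA. Of the 9 PP2C phosphatases 6 were lower in iSB09 than in ABA and 0 higher (0 at an unadjusted p under 0.05, with DESeq2 and with limma voom), with a median log2 fold change of -1.13. Solyc03g096670.3 had a log2 fold change of -2.18 ± 0.12 (adjusted p = 1.7e-05), and Solyc07g040990.4 had -1.51 ± 0.11 (adjusted p = 3.1e-05). Of the 14 receptors 4 were higher in iSB09 and 0 lower (0 at an unadjusted p under 0.05, with DESeq2 and with limma voom), among them Solyc10g085310.1 by 1.12 ± 0.19 (adjusted p = 0.0053). Solyc12g055990.2 was higher by 0.58 ± 0.12 (adjusted p = 0.018), a call that ended without any 1 ABA library or iSB09 replicate 1 (adjusted p = 0.066 to 0.069). The number of receptors higher in iSB09 was 2 without ABA replicate 1 or iSB09 replicate 2, and 1 without ABA replicate 2 or 3 or iSB09 replicate 1. Of 9 LEA, dehydrin and ASR genes 4 were lower, including Solyc02g084850.3 with -2.02 ± 0.19 (adjusted p = 0.00015) and Solyc02g062390.3 with -1.38 ± 0.21 (adjusted p = 0.0027).

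Of 6 bZIP factors 3 were lower in iSB09 than in ABA, with -1.06 ± 0.09 for Solyc04g078840.3 (adjusted p = 0.00014) and -0.61 ± 0.10 for Solyc01g108080.4 (adjusted p = 0.0046). Of 7 clock genes 3 were lower, with -0.67 ± 0.08 for Solyc04g071990.3 (adjusted p = 0.00066) and -0.61 ± 0.12 for Solyc12g056650.2 (adjusted p = 0.011; 0.052 without ABA replicate 2). Omission left 2 lower bZIP factors without mock replicate 2 or 3, ABA replicate 1, 2 or 3, or iSB09 replicate 1 or 2. It left 1 lower clock gene without ABA replicate 2, and 2 without ABA replicate 3 or iSB09 replicate 1 or 2. Of 4 catabolism genes 2 were lower (1 without ABA replicate 1 or iSB09 replicate 3, 3 without mock replicate 3), as were 1 of 5 biosynthesis genes, both NAC and HD-Zip factors, 1 of 2 genes of raffinose, proline and trehalose synthesis, 1 of 4 ethylene and 1 of 3 heat shock genes. None of 7 SnRK2 kinases passed (3 lower at an unadjusted p under 0.05; 0 with DESeq2 and with limma voom), nor any of 4 expansins and xyloglucan endotransglucosylases (2 higher unadjusted, 2 with DESeq2, 0 with limma voom, 1 without mock replicate 3) or 18 jasmonate genes (2 higher and 2 lower unadjusted, 0 with DESeq2 and with limma voom, 1 lower without ABA replicate 3). None of the 15 photosynthesis genes differed, at an unadjusted p under 0.05 or with DESeq2 or limma voom (camera adjusted p = 0.63, or 0.89 with an estimated correlation; 0.027 without iSB09 replicate 2 at the preset correlation), and the root marker, at -0.59 (unadjusted p under 0.05; not with DESeq2 or limma voom), and the gibberellin gene, at 0.16, did not pass.

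Over all genes, 378 were higher and 879 lower in iSB09 than in ABA, 200 and 395 of them at least 2-fold. Among IDs with at least 1 CPM in the higher group and no overlap between libraries, the largest positive fitted values were those of Solyc03g093390.4, with 5.55 ± 1.18 (adjusted p = 0.019), and Solyc03g031590.4, with 3.35 ± 0.47 (adjusted p = 0.0017; 3.96 on the log2 scale without ABA replicate 3). The first varied widely, at 18.95 ± 25 CPM in iSB09 (SD, n = 3), and its call ended with limma voom (adjusted p = 0.27) and without any 1 ABA library (0.063 to 0.092). Without iSB09 replicate 1 its log2 fold change was 3.51. Under the same conditions the largest negative fitted values were those of Solyc04g007585.1, with -4.95 ± 0.44 (adjusted p = 0.00014), and Solyc06g069260.1, with 68 counts in ABA against 3, a ratio of 23.1 (95% interval 7.58 to 115). Without iSB09 replicate 3 the fitted log2 fold change of the latter went from -4.36 to -5.19. Phosphatases (adjusted p = 2.3e-11), LEA proteins (0.00043), bZIP factors (0.0017) and clock genes (0.0032) passed camera downwards and receptors (0.0043) upwards. The phosphatases alone stayed under the threshold of 0.05, before rounding (adjusted p = 0.05 with an estimated correlation); the others did not pass, at 0.11 for LEA proteins, 0.065 for bZIP factors and 0.23 for clock genes and receptors. SnRK2 kinases (0.067; 0.025 without iSB09 replicate 3; 0.23 with an estimated correlation), biosynthesis (0.23) and jasmonate genes (0.23) did not pass camera. With fry SnRK2 kinases passed (adjusted p = 0.038) and receptors did not (0.055). Adjusted over the list alone, 6 phosphatases, 2 SnRK2 kinases, 4 bZIP factors, 1 biosynthesis, 3 catabolism, 6 LEA and 4 clock genes were lower, and 4 receptors and 1 LEA gene were higher. Fewer genes were higher without ABA replicate 1 (213), 2 (181) or 3 (208) or iSB09 replicate 1 (238), and fewer lower without ABA replicate 1 (517) or 2 (529).

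The responses were then compared gene by gene. Of the 2091 genes that ABA raised, 549 were also raised by iSB09, where independent lists of these sizes would share 55, and of the 2120 lowered, 499 were also lowered, against 52.5. Unrelated responses were simulated against shared simulated mock libraries, with lists of 1770 and 498 raised and 1720 and 389 lowered genes on average. There the overlap was 44.1 and 40.2 on average and at most 56 and 53, where independent lists of the simulated sizes would share 41.1 and 31.3. No gene passed in opposite directions (7 raised by ABA and lowered by iSB09, and 1 the other way, at unadjusted p under 0.05; 0 with DESeq2 and with limma voom). Among the 4211 ABA-changed genes, 96.6% had the same sign after iSB09, beside 83.1% among as many top genes in simulated unchanged groups, and 24.9% passed the iSB09 test. The 95% interval of the difference between iSB09 and ABA lay within 1 log2 unit either way for 60.7% of them, but for 19.3% and 19.5% of the genes that ABA raised or lowered at least 2-fold. For smaller changes an absent iSB09 response can also lie within 1 unit. Of the raised genes 847 were lower in iSB09 than in ABA, and of the lowered genes 365 were higher, so that 28.8% changed significantly less. By edgeR 0 changed significantly more (4 raised and 6 lowered further at unadjusted p under 0.05; 1 and 0 with DESeq2, 0 and 0 with limma voom). Changes after iSB09 were smaller in size for 96.2% of ABA-changed genes, beside 82.6% of as many top genes in simulated unchanged groups. Choosing genes by their ABA result favours this. The simulated top genes had no real change, so 83.1% and 82.6% are not the shares that real ABA changes would give. For these shares, neither equal changes nor ABA changes without an iSB09 effect were simulated. The shared mock libraries contribute to the overlap of raised and lowered genes. In the simulations of unrelated responses they added little beside the 549 and 499 genes observed. The excess of the overlap over the simulation is not a measure of shared effect.

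Across the 21424 genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.86 and Spearman's rho of 0.77. Simulated unchanged groups that shared simulated mock libraries gave a mean r of 0.499 and a maximum of 0.527. Genes were drawn independently there, which narrows the spread of r, so that maximum is not a bound. The covariance was 0.337 against a simulated 0.0311, a difference of 0.306. Without mock replicate 2, iSB09 replicate 2 or iSB09 replicate 3, the number of genes lowered by both was 237, 296 or 244, and the share of ABA-changed genes past the iSB09 test without iSB09 replicate 2 or 3 was 16.29% or 16.57%.

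**Figure D2:**
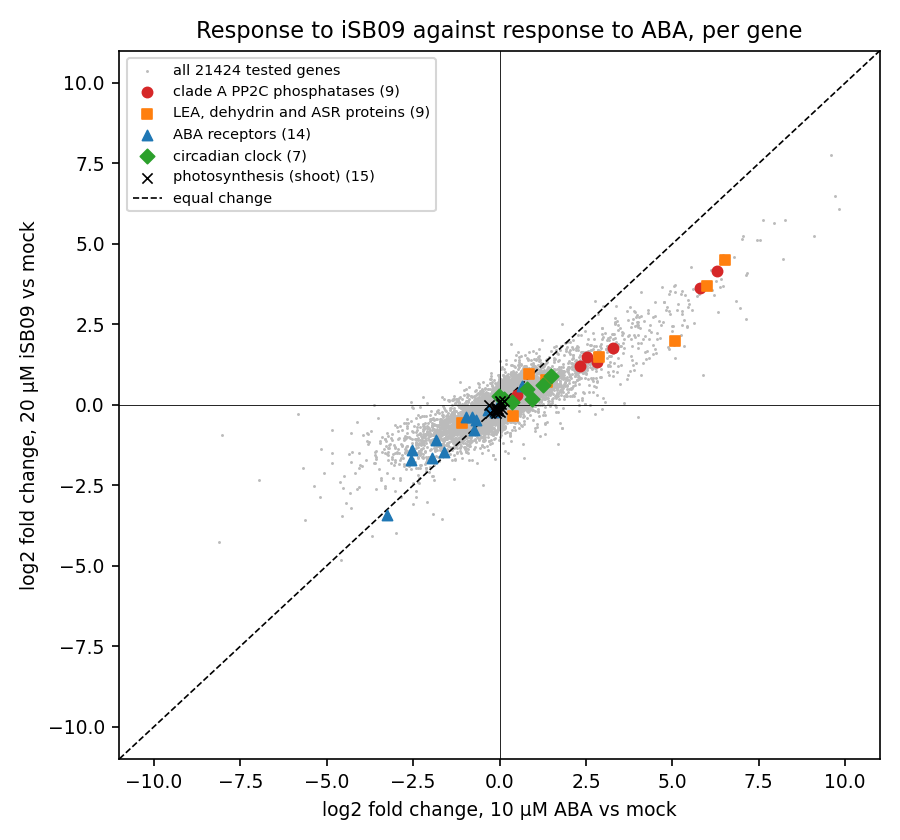
Log2 fold change after 20 µM iSB09 (vertical) against that after 10 µM ABA (horizontal), both relative to mock, for all 21424 tested genes, with 5 gene lists coloured and the dashed line marking equal change. The points run along a line flatter than equal change (r = 0.86 across genes), with list medians, ABA first, of 2.54 and 1.32 for phosphatases, 1.36 and 0.95 for LEA genes, -0.88 and -0.63 for receptors and -0.07 and -0.13 for photosynthesis genes; single members lie elsewhere.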

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

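The alternatives were chosen before the data were examined; the median ratio was not in that plan and was added afterwards. Alternatives for iCB were not run. Tested against a 2-fold change, which only larger changes can pass, ABA raised 514 and lowered 342 genes, iSB09 raised 113 and lowered 25, and iSB09 exceeded ABA in 26 and lay below it in 87. Fitting only the 6 libraries compared left 319 genes lowered by iSB09. Without a filter on low counts the correlation of fold changes was 0.6783, over more genes near the floor. With an estimated correlation 0, 0 and 1 lists passed for ABA, iSB09 and the direct comparison, in place of 5 each. The estimated correlations were 0.02 to 0.89. That of the bZIP list was 0.02, near the preset 0.01. Its camera adjusted p nevertheless went from 0.0021 to 0.07 for ABA against mock. For iSB09 against mock it went from 0.0051 to 0.079, and from 0.0017 to 0.065 for iSB09 against ABA. The lost calls therefore cannot be put down to the size of the correlation alone. What else differs between the 2 forms of camera was not tested. Depth limits what can be seen below 0.045 CPM, or 3 counts over a group.

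Omitting each library in turn, ABA raised 1550 to 2226 and lowered 1288 to 2361 genes (1288 without ABA replicate 2, 1406 without replicate 3). iSB09 raised 410 to 563 and lowered 245 to 651 (245 without mock replicate 2, 311 without iSB09 replicate 2, 249 without iSB09 replicate 3). In the direct comparison 181 to 406 were higher (213, 181 and 208 without ABA replicate 1, 2 or 3, and 238 without iSB09 replicate 1) and 517 to 906 lower (517 and 529 without ABA replicate 1 or 2). Genes lowered by both numbered 237 to 572 (237 without mock replicate 2, 296 and 244 without iSB09 replicate 2 or 3). The correlation was 0.8001 to 0.8771, the same-sign share 94.71 to 97.6%, and the share past the iSB09 test 16.29 to 29.11%. The share within 1 log2 unit was 47.21 to 59.58%. The median ratio of iSB09 to ABA log2 fold changes was 0.4722 to 0.5395, over genes that ABA changed at least 2-fold. Fewer libraries were fitted in each; what else moved the counts was not tested.

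Replicate numbers did not pair the libraries: deviations from group means correlated between -0.18 and 0.34 for 9 pairs of the same number and between -0.36 and 0.39 for 18 other pairs. With a replicate block, ABA changed 3904 genes, iSB09 1006 and 1164 differed directly, against 4211, 1095 and 1257. SnRK2 kinases passed camera with the replicate block for ABA against mock (adjusted p = 0.045) and iSB09 against ABA (0.049), both at the preset correlation; over all libraries without the block, adjusted p = 0.19 and 0.23 with an estimated correlation. For 70 single-gene results, 1329 alternatives gave 1261 calls alike, 59 lost, 9 gained and 0 with the opposite sign. The naming rule chose these genes by small adjusted p or large change in the same libraries, which favours calls alike. For 27 list results, 324 alternatives gave 299, 15, 10 and 0.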

Other observations

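The tests of explanations and of a common fraction described here were chosen after the results were seen, as were the genes named. Genes nearly silent in 1 group were chosen by their counts and their ABA call, which favours values in between for iSB09. Of 23 genes with at most 3 mock counts that ABA raised, 22 had more than 3 counts after iSB09, 9 rose against mock and 21 were lower than in ABA; median counts over 3 libraries were 2 in mock, 18 in iSB09 and 104 in ABA. Of 11 genes with at most 3 counts in ABA that ABA lowered, all 11 had more than 3 in iSB09, 6 fell against mock and 5 were higher than in ABA, with medians of 72, 20 and 1 in mock, iSB09 and ABA.

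By edgeR's quasi-likelihood test, 47 genes passed for iSB09 against mock and not for ABA against mock. All 47 had the same sign after ABA, and 22 of them had unadjusted p under 0.05 for ABA against mock. They were chosen by their iSB09 result against the same mock libraries, which favours the same sign. Of these 47, 3 also passed against ABA in the same direction. Each alternative had its own set: 16 of 141 such genes with DESeq2 and 1 of 46 with limma voom. The counts were 4 of 44, 2 of 13 and 6 of 30 without mock replicate 1, 2 or 3. They were 3 of 54, 1 of 53 and 1 of 49 without ABA replicate 1, 2 or 3. Without iSB09 replicate 1, 2 or 3 they were 19 of 106, 5 of 30 and 4 of 14. Solyc09g011670.4 had log2 fold changes of -0.94 ± 0.16 against mock (SE; adjusted p = 0.0061) and -0.75 ± 0.16 against ABA (adjusted p = 0.02), and -0.19 ± 0.16 for ABA against mock. It passed both tests with DESeq2 and limma voom, but not against ABA without ABA replicate 1 or 3 (adjusted p = 0.086 and 0.06).

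The other 2 genes rested on weaker direct tests. Solyc01g006050.2 had 1.55 ± 0.29 against mock (adjusted p = 0.0098) and 1.08 ± 0.28 against ABA (adjusted p = 0.046). The latter call ended with limma voom (0.083), without mock replicate 1, 2 or 3 (0.062, 0.069 and 0.056), without any 1 ABA library (0.14) and without iSB09 replicate 1 or 2 (0.059 and 0.089). Solyc07g044710.2 had -1.57 ± 0.34 against mock (adjusted p = 0.022) and -1.37 ± 0.34 against ABA (adjusted p = 0.039). The direct call ended with limma voom (0.085), without mock replicate 1 (0.053), without ABA replicate 2 or 3 (0.16 and 0.13) and without iSB09 replicate 1, 2 or 3 (0.097, 0.11 and 0.09). The call against mock ended without mock replicate 2 (0.093) and without iSB09 replicate 2 or 3 (0.076 and 0.062).

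Changes after iSB09 were smaller in size than after ABA for 96.2% of ABA-changed genes, with a median ratio of log2 fold changes of 0.50. This ratio and the fractions below are on the log2 scale and are not shares of a change in CPM. Choosing genes by their ABA result favours smaller changes (82.6% in simulated unchanged groups, which had no real change). Noise with shared mock libraries also gives a ratio near 0.50. The fraction was therefore measured with genes chosen and weighed by 2 mock and 2 ABA libraries, and changes taken from the third of each and from iSB09. Over the 9 choices it was 0.46 to 0.54, which argues against equal changes with larger spread between iSB09 libraries alone, and for single iSB09 libraries 0.40 to 0.59, which argues against 1 library of mock-like material. Lower depth of the iSB09 libraries is argued against by their mean total count, which exceeded that of the ABA libraries by 0.048%. A weaker effect of iSB09 at 20 µM than of ABA at 10 µM remains a hypothesis, which arguments against other explanations do not test. Dose, uptake, receptor selectivity and a difference in harvest time were not tested.

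A further hypothesis was that iSB09 gives 1 fixed fraction of every ABA change on the log2 scale. With the fraction estimated from the covariances, 0.53, 3 of 21424 genes departed from it. Among the 4211 ABA-changed genes alone, 74 departed, 35 weaker and 39 stronger than the fraction, and over the fractions tried the lowest number was 72, at 0.55. An exact common fraction is argued against by those genes, while 98.2% of ABA-changed genes did not pass at 0.53, which does not show that they follow it. In 10 simulations of an exact fraction, at most 1 of the ABA-changed genes departed. By the same test at unadjusted p under 0.05, 17.2% of ABA-changed genes departed from 0.53. In those simulations the share was 6.45% on average and at most 6.95%. Genes were drawn independently there too, so neither maximum is a bound for data with correlated genes. Whether the 74 genes count every departure cannot be told from this share.

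Splits of the 6 libraries of each comparison into 3 and 3 are 10, too few for a share under 0.05. The real split gave 4211 genes for ABA against mock, 1095 for iSB09 against mock and 1257 for iSB09 against ABA, in each case 1 of the 10 splits, and the highest of the other splits gave 0 genes. Every other split mixed libraries of both treatments, so any real difference entered the spread within groups and lowered the number of calls. No conclusion is drawn from the contrast with 0.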
